A study of Homo sapiens with 2 samples.

How the data were processed

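RNA of 2 samples was analysed, SH-SY5Y cells stably carrying an empty vector and SH-SY5Y cells stably carrying a histone H2A type 2-B vector, with 1 array per group. Total RNA was purified, amplified and labelled with Cy3 for a one-colour array of the whole human genome, per the labels' protocols. Both arrays lay on the same slide and shared 1 scan, per the file headers, so slide and scan did not differ between the groups.

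The deposited scanner tables hold a fluorescence intensity per spot, read with Agilent Feature Extraction 10.7, per the submitters' processing notes. Per the file headers, the processed intensity of a spot had its background subtracted and a spatial trend removed within the array, and was not scaled between arrays. The deposited series table holds log2 values of the authors, for which the sources used here do not state the method. Its 2 columns held the same set of values after sorting, within 0.000466, each with a median of 6.67, as quantile normalization between the arrays gives. Each column followed log2 of the processed signal of its own array at a Pearson r of 0.9998 over probes and slopes of 0.987 and 1.01, so the scale is log2 and genes were not centred. These values served as an alternative only.

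Each array held 45015 spots, of which 1639 were controls, and 41000 different probes that were not controls. Spots with an outlier flag for uneven or deviating pixels were left out, 56 on the empty vector array and 89 on the H2AB array, which left 40968 probes with a value on both arrays. The main values are log2 of the processed signal minus the 75th percentile of the array over the probes that were not controls, and spots of the same probe were averaged as log2 values. A probe counted as measured when it was well above background and not saturated on both arrays, which held for 28112 probes. The lowest signal of a probe well above background was 7.34 on the empty vector array and 8.35 on the H2AB array, and the medians of 153 negative control spots were 2.00 and 1.91. The median signal was 96.4 and 108.

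Of 27907 probes with a RefSeq-style accession, 27294 matched the RefSeq gene table of assembly GRCh38.p14 without accession versions and took its symbol, giving 18232 genes. The other 13706 probes stayed unnamed and were left out of gene counts and lists. The array annotation was made on build hg19, per the file headers, so no coordinates are printed and the table served only for names and for the order of genes. The value of a gene is the mean over its measured probes, with the SD over probes. Levels of XIST and of Y-linked genes are not reported.

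With 1 array per group no test across samples can be made. A gene was called higher or lower at a log2 difference of at least 1, a 2-fold difference, among 13608 measured genes. A gene with every probe below background on 1 array is given as an at-least fold. The bright value was set against the higher of the lowest well-above-background signal of the dim array and the dim probe's own signal. Technical error comes from 264 probes printed 10 times per array.

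Before the data were examined, 43 gene lists with 1377 entries were fixed, covering histones, chromatin regulators, neuroblastoma identity, neuronal function, signalling, stress, metabolism, control genes and markers of other cell types. Of these entries 6 had no single gene in the reference table. A list's median was placed among 10000 random lists of the same size matched on mean level in 20 bins, and stood apart below percentile 2.5 or above 97.5. The rule for named genes, fixed at the same time, took the 12 largest differences each way among measured genes whose probes agreed in direction. It added the 6 largest bounds each way, the transfected gene, and up to 4 measured members per list with the largest differences, 189 genes in all, of which a few are not reported here.

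Calling and list steps were tested on simulated data, in which 200 of 13608 genes were changed for H2AB against empty vector. Simulated H2AB values were the empty vector levels plus noise of the size of the spread between repeated spots. All 50 genes were called at each log2 change of 1.5, 2, −1.5 and −2, with 0 false calls among 13408 unchanged genes. With noise this small that outcome was nearly fixed in advance, and it gives no rate of false calls between cultures. Scaling, background and detection steps were not simulated. Of 200 random lists of 25 genes, 7.5% stood apart where 5% is the nominal share.

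The alternatives were normexp background correction (offset 50), median scaling, quantile normalization, intensity-dependent loess (span 0.3), the authors' deposited values, no filter on dim probes, a floor 4 times higher, the brightest probe of a gene, and random lists matched in 10 bins. The planned normexp setting named the mean pixel signal, and the median pixel signal was used in its place. In the setting with no filter, signals below the lowest well-above-background signal of their array were raised to it. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and statsmodels 0.14.6, and R 4.3.3 with limma 3.58.1 for normexp.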

Results

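Gene expression was measured in SH-SY5Y, a human neuroblastoma cell line of sympathetic noradrenergic origin, carrying either an empty vector or a vector for histone H2A type 2-B, which the labels call H2AB. Histone H2A is one of the core proteins around which DNA is wrapped in the nucleosome. Both lines had been selected for stable integration of the vector with neomycin. Total RNA of each line was labelled with Cy3 and hybridised to 1 one-colour oligonucleotide array, so there was 1 array per group. No difference given here has a replicate check, no p-value is given, and the number of arrays limits the precision of every value. Differences are log2 values of the H2AB array minus the empty vector array, and an error after ± is the SD over the different probes of 1 gene.

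The empty vector array held 29723 probes well above background, 72.5% of the 41000 probes that were not controls, and the H2AB array held 30672, or 74.8%. The 75th percentile of the signal was 734 on the empty vector array and 718 on the H2AB array. No spot was saturated on either array. Among 200 measured probes printed 10 times on each array, the median SD between spots was 0.06 log2 units on the empty vector array and 0.07 on the H2AB array. The difference between the arrays from 1 spot had a pooled SD of 0.11 within a probe, which was 0.15 for the dimmer probes and 0.06 for the brighter ones. None of the 1945 spots lay 2-fold or more from the mean difference of its probe, 0 spots. With spots taken as independent that allows a share of up to 0.154%, but they repeat only 200 probes, so the limit may be too low. The spread between spots covers their printing and reading and leaves out culture, extraction and labelling.

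The first question was whether the line labelled H2AB held more transcript of the histone gene it was made to carry. The gene of histone H2A type 2-B is H2AC21 (older name HIST2H2AB, RefSeq NM_175065). H2AC21 was 1.42-fold higher on the H2AB array, a log2 difference of 0.51 ± 0.08 over 2 probes, which did not reach the 2-fold threshold used for calls. Probe A_23_P343927 read 354 on the empty vector array and 473 on the H2AB array, and probe A_24_P68631 read 6557 and 9501. Both differences were larger than the spread between repeated spots, which leaves out culture, extraction and labelling. They were small beside the SD of 1.43 of the difference over all measured genes. H2AC20, another replication-dependent H2A gene, differed by 0.36 and 0.54 on its 2 probes, so a rise of this size was not particular to the H2AC21 probes. Probes of similar H2A genes may read the vector's transcript too, so this does not decide where the rise came from. Other H2A genes went both ways, as given below. The sequences of the probes were not used here, so a probe outside the cloned part of the gene would not read the vector's transcript.

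Other genes of the histone clusters moved both ways. H2AC19, whose product is also a replication-dependent H2A, was higher by 2.04 ± 0.32 over 2 probes, and H2AC7 was higher by 1.02. H2AC8 stood at −1.21 and H2AC15 at −1.10. H2AC16 was well above background only on the empty vector array, at least 33.4-fold brighter there. Of the 12 measured H2A genes other than H2AC21, 2 were at least 2-fold higher and 2 at least 2-fold lower. The list had a median of −0.55, at percentile 2.03 of 10000 random lists matched on level, but at percentile 8.25 under normexp background correction. The H1, H3 and H4 genes had a median of −0.51 over 27 measured members (percentile 0.63), with 9 lower and 1 higher. H1-3, a linker histone, stood at −2.84, H3C11 at −2.55, H4C11 at −2.07 and H3C4 at −2.03 ± 0.46, while H1-2, named after its value was seen, was higher by 1.68. Of 11 measured H2B genes, 2 were higher and none was lower: H2BC12 by 2.35 and H2BC21 by 1.28 ± 0.53 over 3 probes. H2BC14 differed by 0.96 and H2BC5 by 0.68. The H2B median of 0.42 lay at percentile 97.3, inside the limits, and passed the upper limit under quantile normalization, at percentile 98.8, and under 4 other alternatives. Copies of replication-dependent histone genes are similar in sequence, and probes may read more than 1 of them.

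**Figure D1:**
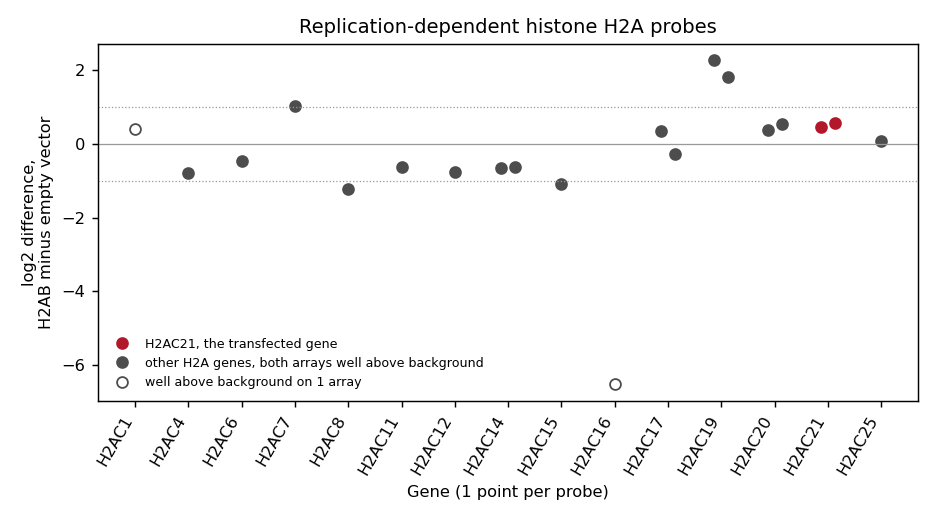
Differences of probes for replication-dependent histone H2A genes, 1 point per probe, with the gene on the horizontal axis and the log2 difference between the H2AB and empty vector arrays on the vertical axis. Filled points were well above background on both arrays, open points on 1 array only (drawn at the measured signals), red points are the probes of H2AC21 at 0.45 and 0.57, and dotted lines mark a 2-fold difference.

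The main comparison asked which genes differed between the line with the histone vector and the line with the empty vector. The lines differed at least 2-fold in 27.55% of the genes measured in both. Of 13608 genes measured on both arrays, 1978 (14.5%) were at least 2-fold higher and 1771 (13.01%) at least 2-fold lower on the H2AB array. At least 4-fold differences were found for 724 genes in the higher and 693 in the lower direction, and at least 32-fold differences for 80 and 120. The SD of the difference over genes was 1.43, and levels correlated at a Pearson r of 0.86 across genes, which are not independent replicates. Of the 5009 genes with several measured probes, 1179 were called, and in 1159 of these every probe differed in the same direction. The calls rest on the mean of the same probes, which favours such agreement. The counts under normexp background correction were 1345 higher and 1282 lower genes.

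Among the genes furthest below their empty vector level, DLK1, a transmembrane protein of the Notch ligand family, was 1787.5-fold lower, at a log2 difference of −10.80, and BEX1, a brain-expressed adaptor, stood at −10.53. ELAVL4, a neuronal RNA-binding protein, was 1170-fold lower (−10.19). STMN2, a microtubule regulator of growth cones, was 818.7-fold lower (−9.68) and was still well above background on the H2AB array, at −1.87 relative to the 75th percentile. CYB561, a cytochrome of chromaffin granules, stood at −9.80 ± 0.46 over 2 probes, and NSG2, a neuronal vesicle protein, at −9.10. The cancer-testis antigens MAGEA2B and PRAME stood at −10.00 and −9.43. EFS was lower at −9.93, MARCHF11 at −9.51 and MFAP4, an extracellular matrix protein, at −9.20.

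At the other end, SELENOP, a secreted selenium carrier, was 1829-fold higher on the H2AB array, a difference of 10.84. HES5, a repressor induced by Notch signalling, was 560.0-fold higher (9.13). The S100 family genes S100A10 and S100A11 were higher by 8.57 and 8.04. HLA-DPB1, a chain of an MHC class II molecule, was higher by 8.25, the lectin gene CHODL by 8.08 and the GTPase gene RAB34 by 8.03. POU4F1, a transcription factor of sensory neurons, was higher by 7.89, and the desmosomal p53 target PERP by 7.63. DMKN was higher by 7.37, CCDC8 by 7.30 and the homeobox gene HOXA5 by 7.16. The dim side of most of these differences lay near the floor of detection, which was −6.64 on the empty vector array and −6.43 on the H2AB array. Under normexp background correction SELENOP stood at 7.93.

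Further genes were well above background on only 1 array, so that their difference is a lower bound, computed against the higher of the dim array's detection floor and the dim probe's own signal. A bound of at least 2-fold was found for 817 genes detected only on the H2AB array and for 450 detected only on the empty vector array. DBH, the enzyme that makes noradrenaline from dopamine, was at least 2689.8-fold lower on the H2AB array. The transcription factor genes TFAP2B and SOX11 were at least 2025-fold and 712-fold lower, and the vesicle protein gene SYT4 at least 822-fold. SERP2 and TSTD1 were at least 518-fold and 436-fold lower. On the H2AB array alone, CA2, a carbonic anhydrase, was at least 1841-fold higher and YBX3, a cold shock domain protein, at least 1220.2-fold. SLC18B1, a vesicular polyamine transporter, was at least 945-fold higher and SLFN11, a regulator of the response to DNA damage, at least 830.4-fold. DSP, a desmosomal plaque protein, was at least 820.3-fold higher and HOXA9 at least 794-fold. Under normexp background correction the counts of such bounds were 411 for the H2AB array alone and 242 for the empty vector array alone.

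**Figure D2:**
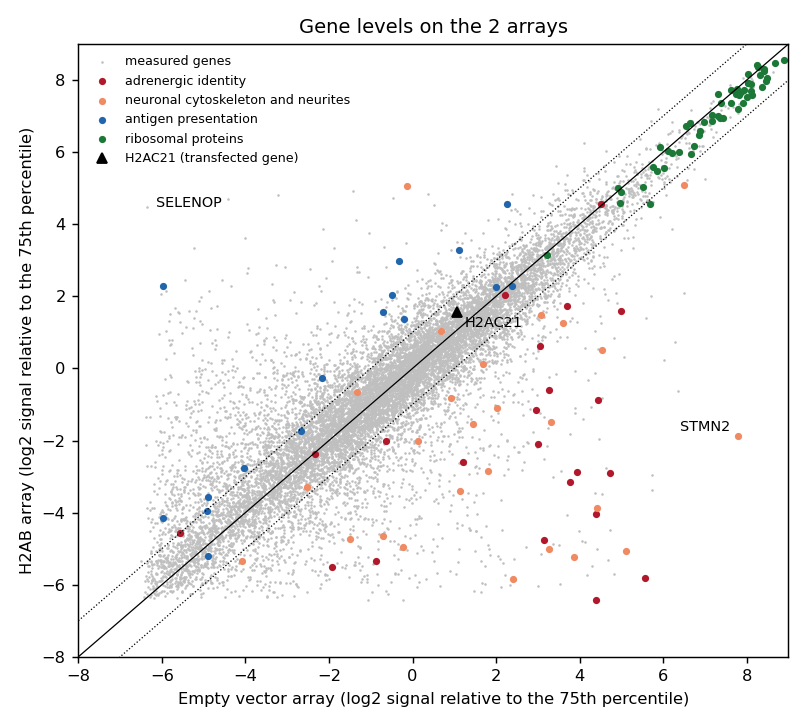
Levels of measured genes on the empty vector array (horizontal axis) and on the H2AB array (vertical axis), each as log2 signal relative to the array's 75th percentile, with 1 array per group and 1 point per gene. Dotted lines mark a 2-fold difference: most adrenergic and neuronal cytoskeleton genes lie below them (18 of 22 and 22 of 26), 1 of the 54 ribosomal protein genes does, and H2AC21 lies between them at 0.51.

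Genes of noradrenergic identity were lower as a group. Of 22 measured members of this list 18 were at least 2-fold lower and none was higher, with a median of −3.99, a 15.9-fold difference, below all 10000 random lists (percentile 0). Besides DLK1, DDC, an enzyme of catecholamine synthesis, stood at −8.42 and the secretory granule protein CHGB at −7.91. A further 9 members were detected only on the empty vector array at a bound of at least 2-fold, and with these at their bounds the median was −5.33. The 4 measured members that were not called, named after their values were seen, were PHOX2A at 0.06, TH at −0.03, HAND1 at −0.16 and INSM1 at 0.995. PHOX2A was bright on both arrays, at 4.50 and 4.56 relative to the 75th percentile.

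Neuronal cytoskeleton and neurite genes were also lower, 22 of 26 measured members with a median of −3.18 (percentile 0). ELAVL4 and STMN2 led the list, followed by the neurofilament genes NEFH at −9.08 and NEFM at −8.29. The single higher member, named after its value was seen, was BASP1, a growth cone membrane protein, at 5.22. Of 21 measured genes of synaptic vesicles and exocytosis, 14 were lower and none higher, with a median of −2.07 (percentile 0). SCG3, a granin, stood at −7.02 ± 1.20, the vesicle GTPase RAB3C at −6.17, SYT11 at −6.13 ± 0.66 and UNC13A, a priming factor for release, at −5.56. Neurotrophin receptors and retinoic acid response genes had a median of −2.39 over 20 measured members (percentile 0), with 12 lower and 1 higher. STRA6, a receptor for retinol uptake, stood at −7.55, the receptor tyrosine kinase RET at −6.92 and the retinoic acid-binding protein CRABP1 at −5.36, while DHRS3, a retinaldehyde reductase, was higher by 6.97. In that list 7 members were detected only on the H2AB array and 1 only on the empty vector array at a bound of at least 2-fold, and with bounds the median was −0.84.

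Axon guidance and neural adhesion genes went both ways. Of 28 measured members 8 were higher and 10 lower, with a median of 0.01 (percentile 40.3). A further 12 members were detected only on the H2AB array and 3 only on the empty vector array at a bound of at least 2-fold, and with bounds the median was 0.96. SLIT3, a guidance cue, stood at −5.80 and UNC5A, a netrin receptor, at −3.02, whereas SLIT2 was higher by 5.25 and NRP1 by 4.26 ± 2.15 over 3 probes. The place of this list depended on dim genes: its median was −0.55 (percentile 0.13) under the stricter filter and 0.58 (percentile 99.89) with no filter. In the setting with no filter, dim signals were raised to each array's own floor, which was higher on the H2AB array.

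Cancer-testis antigens, germline genes that are often silenced by DNA methylation, were lower in 9 of 13 measured members, with a median of −1.54 (percentile 0). MAGEA12 stood at −9.05 and CSAG1 at −8.51, beside MAGEA2B and PRAME. At a bound of at least 2-fold, a further 7 were detected only on the empty vector array and 0 only on the H2AB array. The single higher measured member, named after its value was seen, was TKTL1 at 1.90. Under the stricter filter the median was −0.79 at percentile 4.35.

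Mesenchymal genes, which mark substrate-adherent neuroblastoma cells, were higher as a group but not uniformly. Of 21 measured members 12 were higher and 5 lower, with a median of 1.14 (percentile 99.99). S100A11 was higher by 8.04 and CCN1, a matricellular protein, by 5.34 ± 0.04, while TWIST1, a transcription factor of mesenchymal cells, stood at −4.35 ± 0.31 and the lectin gene LGALS1 at −3.55. In addition 9 members were detected only on the H2AB array and 3 only on the empty vector array at a bound of at least 2-fold. Extracellular matrix and integrin genes had a median of 0.83 over 39 measured members (percentile 100), with 18 higher and 8 lower. NID2, a basement membrane protein, was higher by 6.51, and the integrin chains ITGA5 and ITGA6 by 3.99 and 3.70, while NCAN, a proteoglycan of nervous tissue, stood at −5.67.

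HOX genes, which pattern the body axis, were detected more often on the H2AB array. Of 18 measured members 8 were higher and 3 lower, and 16 more were detected only on the H2AB array against 0 only on the empty vector array at a bound of at least 2-fold. HOXB13 was higher by 4.36, HOXD11 by 3.88 and HOXD10 by 3.32, beside HOXA5. The measured median of 0.64 lay at percentile 98.6, but at percentile 96.4 under quantile normalization. With bounds the median was 2.82.

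Antigen presentation genes were higher in 11 of 16 measured members and lower in none, with a median of 1.70, a 3.25-fold difference (percentile 100). The MHC class I genes HLA-B, HLA-E and HLA-G were higher by 3.31 ± 0.11, 2.53 ± 1.56 and 2.30, beside the class II gene HLA-DPB1. A further 6 members were detected only on the H2AB array at a bound of at least 2-fold. MHC class I genes are similar in sequence and their probes may read more than 1 of them. Interferon response genes had a median of 0.90 over 25 measured members (percentile 99.9), with 11 higher and 2 lower. IFITM2 and IFITM3, membrane proteins that restrict virus entry, were higher by 5.69 and 4.81, the protease gene USP18 by 4.57 ± 0.63 and the helicase gene DDX60 by 3.27 ± 0.49. The lower members, named after their values were seen, were OAS3 at −3.10 and RSAD2 at −1.52. These 2 lists stood beside an adrenergic list at −3.99 on the same arrays.

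**Figure D3:**
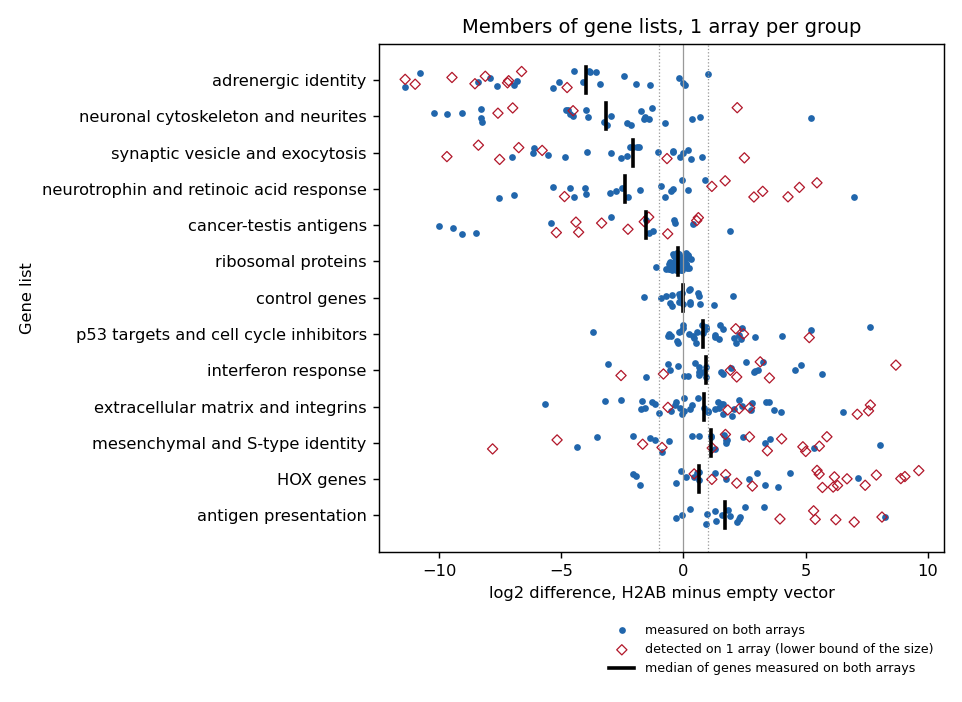
Differences of single genes in 13 of the gene lists, 1 line per list, on a log2 axis of the H2AB array minus the empty vector array, with 1 array per group. Filled points were measured on both arrays, open diamonds are lower bounds for genes detected on 1 array, bars are medians of measured genes and dotted lines mark 2-fold: medians run from −3.99 for adrenergic identity to 1.70 for antigen presentation.

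Among cell cycle genes, p53 targets and inhibitors of cyclin-dependent kinases were higher in 14 of 33 measured members and lower in 1, with a median of 0.79 (percentile 100). GADD45B, a stress-induced growth inhibitor, was higher by 5.22 ± 1.31 and CDKN2A, which encodes the tumour suppressors p16 and ARF, by 4.03 ± 0.59, beside PERP. TP53I3 was the lower member, at −3.72. Genes of mitosis had a median of 0.21 over 37 measured members (percentile 98.5), with 3 higher and 2 lower. CENPM was higher by 1.22 and CDC25C by 1.16, whereas the phosphatase gene CDC25B stood at −2.06 and the proliferation marker MKI67 at −1.07. With the brightest probe of each gene this median was 0.15 at percentile 95.3. Genes of DNA replication did not stand apart, with a median of 0.04 over 42 members (percentile 82.6), 3 higher and 2 lower. CCND1, cyclin D1, stood at −3.83 ± 0.59 and the kinase gene CDK6 at −1.06 ± 0.14, while E2F7 was higher by 1.68 and RBL1 by 1.55 ± 0.12.

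MYCN and MYC targets had a median of −0.30 over 30 members (percentile 7.45), with 2 higher and 4 lower. TERT, the catalytic subunit of telomerase, stood at −1.92 and RRS1 at −1.30, MDM2 was higher by 1.48 ± 0.27, and the probes of MYCN itself disagreed, at −1.64 ± 2.00. Apoptosis regulators went both ways, 8 higher and 6 lower of 33 with a median of 0.02 (percentile 62.3). The survival gene BCL2 stood at −3.96, while BMF was higher by 1.61. HRK was at 1.80 ± 2.61 over 2 probes that disagreed, and at −0.05 from its brightest probe. DNA damage repair genes had a median of 0.17 over 33 members (percentile 93.8), with 3 higher and 1 lower. LIG4 was higher by 1.59, MRE11 by 1.14 ± 0.01 and XRCC6 by 1.03 ± 0.08.

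Of the chromatin lists, none of the remaining 3 stood apart. Histone variants had a median of −0.36 over 12 members (percentile 11.6), with 2 lower. H2AJ stood at −1.30 ± 1.54, the centromeric variant CENPA at −0.89 and H3-3A at −0.52 ± 0.18. Histone chaperones and H2A modifiers had a median of −0.01 over 28 members (percentile 57.8), with 1 higher and 2 lower. CHAF1B, a subunit of chromatin assembly factor 1, was higher by 1.69, whereas NAP1L3 stood at −2.86, the H3.3 chaperone DAXX at −1.38 and NPM3 at −0.99. Polycomb and DNA methylation genes had a median of 0.02 over 18 members (percentile 58.7), with 3 higher and 1 lower. CBX7 was higher by 2.21 ± 0.06, RBBP7 by 2.14 and TET1 by 1.04, while the probes of DNMT3A disagreed, at −1.79 ± 1.95.

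Hypoxia and glycolysis genes were lower in 10 of 33 measured members and higher in 4, with a median of −0.48 (percentile 0.26). The neuronal enolase ENO2 stood at −4.65, the brain aldolase ALDOC at −2.96, the hypoxia-inducible factor EPAS1 at −2.42 ± 0.17 and ANKRD37 at −2.19. With no filter on dim probes the median was −0.17 at percentile 12.9. Oxidative phosphorylation genes had a median of 0.14 over 41 members (percentile 99.3), with 3 higher and 1 lower. SDHA was higher by 2.03 ± 0.04, ATP5PO by 1.31 and SDHC by 1.18. Cholesterol and fatty acid synthesis genes were lower in 8 of 30 and higher in 1, with a median of −0.22 (percentile 12). The desaturase gene FADS2 stood at −3.28 ± 0.51 and the regulator SREBF1 at −1.69 ± 0.09.

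Among stress responses, oxidative stress genes were higher in 7 of 33 and lower in 2, with a median of 0.25 (percentile 97.45) that passed the upper limit under the stricter filter (percentile 97.65). HMOX1, heme oxygenase, was higher by 4.14, SOD2 by 2.10 and the metallothionein MT2A by 1.76 ± 0.16, and the ferritin chain FTL was 2.83-fold lower. Heat shock genes had a median of −0.20 over 14 members (percentile 28.8), with 3 higher and 4 lower. HSPA1A was higher by 4.81 ± 0.05 over 3 probes, its cochaperone BAG3 by 2.88 ± 0.16 and HSPA4L by 1.43, whereas HSPH1 stood at −1.86. Unfolded protein and amino acid stress genes had a median of 0.07 over 35 members (percentile 81.4), with 5 higher and 6 lower. SESN2 was higher by 2.41, while STC2 stood at −2.36 ± 0.35, CHAC1 at −1.87 and TRIB3 at −1.56 ± 0.04.

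Signalling lists held large differences in both directions and did not stand apart. Notch pathway genes were higher in 9 of 24 and lower in 6, with a median of 0.29 (percentile 91.6). DLL1, a Notch ligand, was higher by 5.84 beside HES5, whereas DTX1 stood at −6.20 beside DLK1. Wnt pathway genes were higher in 12 of 37 and lower in 6, with a median of 0.32 (percentile 95.9), which passed the upper limit under normexp background correction (percentile 98.7). WNT10B was higher by 3.92, the Wnt antagonists DKK3 and FRZB stood at −5.17 ± 0.32 and −4.53, and the probes of NKD2 disagreed, at 4.11 ± 5.18. TGF-beta and BMP genes had a median of 0.01 over 25 members (percentile 48.6), with 5 higher and 7 lower, and 10 were detected only on the H2AB array and 2 only on the empty vector array at a bound of at least 2-fold. ID4 was higher by 5.15, the ligand BMP2 by 4.96 and the receptor gene TGFBR2 by 3.52.

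Immediate-early genes and MAPK feedback genes were higher in 8 of 28 and lower in 8, with a median of 0.15 (percentile 74.6). The feedback inhibitors DUSP6, SPRY4 and SPRED2 stood at −6.39, −5.27 and −2.49, and the neuronal activity gene ARC at −2.74. NF-kB and cytokine genes had a median of −0.04 over 16 members (percentile 36.1), with 3 higher and 4 lower, and with bounds the median was 0.38. The chemokine receptor CXCR4 stood at −4.76 and TNFAIP2 at −3.03, while TRAF1 was higher by 2.44 ± 0.12 and SOD2 by 2.10. Angiogenesis factors had a median of −0.33 over 17 members (percentile 5.73), with 4 higher and 6 lower, and under the stricter filter the median was −0.43 at percentile 1.51. PDGFC was higher by 6.14, CCN1 by 5.34 ± 0.04 and NRP1 by 4.26 ± 2.15, and PTN, pleiotrophin, stood at −5.87 ± 0.01. Matrix degradation and invasion genes were higher in 9 of 26 and lower in 7, with a median of −0.04 (percentile 34.6). SERPINE2, an inhibitor of serine proteases, was higher by 4.58, the protease ADAMTS5 by 3.96 and the plasminogen activator PLAT by 3.94, and ADAMTS9 stood at −4.46 ± 0.12.

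The fixed lists of markers of glial, epithelial, blood and endothelial cells did not stand apart in the main setting. Their percentiles cover only genes measured on both arrays. Schwann and glial markers had a median of −0.23 over 8 measured members (percentile 18.0), with SOX2 higher by 5.11 ± 0.26, NES at −3.42, PMP22 at −0.74 and the probes of GFRA3 at −2.53 ± 1.84. Of these markers 5 were detected only on the H2AB array and 1 only on the empty vector array at a bound of at least 2-fold, and with bounds the median was 0.33. Epithelial markers had a median of −0.36 over 13 members (percentile 6.48), with EPCAM higher by 1.62, KRT19 at −4.83, SPINT1 at −1.87 and CDH3 at −1.29. Blood cell markers had a median of 0.30 over 9 members (percentile 77.7), with HBA1 higher by 2.27, CD8A at −2.23, HBA2 at 0.96 and CD79A at 0.39. Endothelial markers had a median of 0.54 over 9 members (percentile 91.3), or 1.08 under the stricter filter (percentile 98.2). VWF was higher by 4.13, EGFL7 by 1.68 and SOX17 by 1.17, and ENG stood at −4.32.

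Genes often used as expression controls had a median of −0.02 over 20 members (percentile 70.7). SDHA was higher by 2.03 ± 0.04 and GUSB was 2.38-fold higher, and TFRC stood at −1.63 and TUBB at −0.92 ± 0.29. Of 54 ribosomal protein genes none was higher and 1 was lower, and the median of −0.22 lay at percentile 24.5 of random lists of equally bright genes. RPL34 stood at −0.70 ± 0.27, RPS25 at −0.60 ± 0.13 and RPS20 at −0.58. In all, 16 of 42 lists stood apart, 8 higher and 8 lower, and 11 of the 16 stood apart under every alternative setting. For lists of independent genes, 2.1 would be expected at the nominal 5% and 3.15 at the 7.5% of random lists in simulated data. Members of the fixed lists may vary together and some genes sit in more than 1 list, so these numbers give no chance level for the 16. The percentiles describe these 2 arrays and carry no replicate error.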

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

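Probes without a gene name entered no gene count or list, and they also differed between the arrays. Of 7727 such probes measured on both arrays, 1064 were at least 2-fold higher on the H2AB array and 742 at least 2-fold lower. They were singled out because they are a signal outside the named genes that the comparison rests on. No biological explanation was tested for them.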

How the results depend on the processing

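All alternatives but normexp were planned before the data were examined. Normexp was planned on the mean pixel signal, which was not run because the files lack it, and its use on the median pixel signal was chosen after the files were seen. The numbers of higher and lower genes stayed within 1.5 times their main values in every alternative run. They ran from 1345 and 1282 under normexp background correction to 2763 and 2194 with no filter on dim probes. With no filter, signals below an array's floor were raised to it, −6.64 on the empty vector array and −6.43 on the H2AB array. A gene below both floors took a difference of 0.22 from the floors alone, which was also the median of all genes. That offset favours higher over lower calls in this setting. Of the 3749 genes called, all kept their sign under normexp, median scaling, quantile normalization, loess and the authors' deposited values. With no filter on dim probes 3748 kept it and with the brightest probe 3737, and under the stricter filter 2963 of the 2969 still measured did. Under normexp 2608 of them were still at least 2-fold apart, and under the deposited values 3451. The transfected gene lay between 0.41 and 0.57 in every alternative run. Under normexp the genes detected on 1 array at a bound of at least 2-fold numbered 653 against 1267, with 411 on the H2AB array alone and 242 on the empty vector array alone. That setting changed the pixel signal, the background correction and the offset together, and their separate parts were not tested. HRK reversed to −0.045 with its brightest probe because its 2 probes differed. Of 1452 values of named genes under alternatives, 482 moved by more than the spread between spots. The places of 14 lists changed under some alternative. Besides those given with the lists, the replication-dependent H2B genes passed the upper limit under loess (percentile 98.6), the deposited values (98.7), the stricter filter (97.9) and 10 bins (97.87). The unfolded protein list passed it under normexp (97.86), the Notch list with no filter (99.6), the Wnt list under quantile normalization (98.5) and the deposited values (98.6), and the DNA damage repair list with the brightest probe (98.1). HOX genes lay at 96.6 under the deposited values. The causes of these list changes were not tested. Keeping saturated probes was not run because no spot was saturated, and genes detected on 1 array have no count without a filter. No paired analysis was possible because each group had 1 array, and leaving out an array was impossible for the same reason. Signals near background limit the largest folds: DBH stood at −8.72 under normexp against −11.39.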

Other observations

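The tests in this part were chosen after the results were seen, except those of neighbouring genes and of higher background in corrected signals, whose outcomes were written down before they were run. The 12 marker lists of other tissues were chosen after the main results and before their own test.

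Single members of the retina list, which did not stand apart as a list, differed in both directions. PAX6, an eye and brain factor, was detected only on the H2AB array, at least 97.3-fold higher. LHX2, another forebrain and eye factor, was higher by 6.93 and the lens crystallin gene CRYGD by 7.14. SIX3 stood at −4.46, and SIX6 was detected only on the empty vector array, at least 25.2-fold brighter there. The growth factor receptor gene PDGFRA stood at −4.85, and PDGFRB was detected only on the empty vector array, at least 91.0-fold brighter there. These genes were picked after their values were seen.

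Of the 12 lists for other tissues, only the fibroblast list stood apart, with a median of −1.37 over 9 measured members (percentile 0.015). Of its 16 genes, 11 are shared with the fixed lists. Medians and percentiles here rest on genes measured on both arrays, so genes detected on only 1 array could not make a list stand apart. The Ewing sarcoma list had a median of 0.84 over 6 members (percentile 95.4), and at a bound of at least 2-fold 8 of its 18 genes were detected only on the H2AB array, among them NR0B1 at least 179-fold higher and SLFN11, and 1 only on the other. The retina list had a median of 0.60 (percentile 86.3), the squamous list 0.40 (percentile 79.7), the skeletal muscle list 0.30 (percentile 68.6) and the melanocyte list 0.39 (percentile 65.9). The embryonic kidney list lay at 0.04 (percentile 48.6), with 6 of 16 genes at such bounds only on the H2AB array and 0 only on the other, the hepatocyte list at −0.03 (percentile 37.0) and the sensory neuron list at −0.25 (percentile 17.9). The astrocyte list lay at −0.41 (percentile 13.04), with 5 of 15 genes at such bounds only on the H2AB array and 1 only on the other, and the breast list at −0.45 (percentile 7.42). The intestine list had 2 measured genes, with a median of 0.23, and no percentile.

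Neighbouring genes differed together along the genome. In gene order, 86 of 328 blocks of 40 measured genes had a median outside the limits from permuted order, where 100 permutations gave a mean of 16.4 blocks and at most 25. Among genes that differed by less than 2-fold, 47 of 238 blocks did so, against a mean of 11.9 and at most 20. The block from MTFR2 to KATNA1 had a median of 1.02, with 38 of 40 genes above 0, and the block from EPCIP-AS1 to PCP4 one of 1.004, with 37. The block from ZNF14 to FAAP24 had a median of −0.80, with 9 genes above 0, and the block from HADHB to SUPT7L one of −0.63, with 6.

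The pattern most worth following up is the loss of noradrenergic and neuronal transcripts from the array labelled H2AB. The tables argue against spot noise, since 0% of repeated spots lay 2-fold from their mean, and against a minority of other cells, whose dilution could not lower the adrenergic median to −3.99. An exchange of the 2 labels would place the loss in the empty vector line and would not by itself account for it. Whether the labels were exchanged cannot be told, since the transfected gene, which should mark the vector, differed by 0.51, less than 2-fold. RNA of a cell line other than SH-SY5Y on the H2AB array remains a candidate explanation, since it needs neighbouring genes to differ together as they did in 86 blocks, but a subclone with altered copy numbers or regional regulation may give blocks too, and PHOX2A, read by 1 probe, was as bright on both arrays. A switch to the mesenchymal state cannot be told apart from these: 67.6% of the detected mesenchymal genes, 23 of 34 with bounds of any size, were brighter on the H2AB array, between the limits set for and against it, and other values went both ways. The extracellular matrix and integrin list was higher, at 0.83, while LGALS1 and the fibroblast list, which includes TWIST1 and had a median of −1.37, were lower. An effect of the histone vector stays open and untested, because line and vector coincide in 1 array each.

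The second pattern is that the transfected gene differed by less than 2-fold. Saturation of its probes is argued against, since the brighter probe lay 33.1 times below the brightest signal on the H2AB array. Probes that miss the transfected sequence stay open, since the dimmer probe differed by 0.45 and probe sequences were not used here. Low expression from the vector also stays open and was not tested.

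The third pattern is that more genes were detected only on the H2AB array than only on the empty vector array, at a ratio of 1.82 among genes with a bound of at least 2-fold (817 and 450) and of 1.65 among all genes detected on only 1 array. A higher uncorrected signal of empty spots on the H2AB array is argued against: it differed by −0.074 over the 153 negative control spots (95% bootstrap interval −0.085 to −0.042). Higher background in corrected signals cannot be told apart, since background correction acts on them. There the negative control spots differed by −0.041 (95% interval −0.054 to −0.018) and 8704 undetected probes by −0.03, and the outcome written against it needed these probes to be brighter. An effect of the detection threshold at dim levels cannot be told apart. The ratio for such bounds was 1.58 with a floor 4 times higher, but both floors rose by the same factor. The gap between the floors, −6.64 on the empty vector array and −6.43 on the H2AB array, therefore stayed. It can enlarge the bounds of genes detected only on the H2AB array. The ratio for such bounds was 1.38 under quantile normalization, so its size depends on the scaling. A biological difference between the lines stays open and untested.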
